A study of Mus musculus with 12 samples.

How the data were processed

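RNA was measured in 12 libraries from sorted fetal liver cells of floxed Jag1 mouse embryos, 6 from HSCs and 6 from CD169+ macrophages, with 3 Vav-Cre negative and 3 Vav-Cre positive libraries in each. Per the labels' protocols, 2000 HSCs per library, or 1000 to 3000 macrophages, were sorted into lysis buffer, RNA was extracted with a column kit for very small samples including DNase treatment, and full-length cDNA libraries were made in 1 batch per sort with the SMART-Seq v4 kit, which does not mark strand. For macrophages the labels give 1 ng of RNA as input and 11 cycles of amplification. Replicates carry the numbers of the sample titles. The replicate numbers were checked for pairing, and the outcome stands with the alternatives.

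The deposited values are raw read counts per gene, whole numbers that the authors did not normalize, in 1 table per sort. For the HSC table, reads were aligned with STAR 2.7.6a and counted with featureCounts of Subread 2.0.1 on GRCm38 (mm10), per the submitters' processing notes. For the macrophage table the notes name only mm10, and the aligner and counting tool are not given in the sources used here. Settings for strand, multiply mapped reads and the annotation release are not given in the sources used here either. Reads of overlapping or antisense genes could therefore not be told apart, and ribosomal protein and histone genes, which have near-identical pseudogene or family copies, are uncertain to the extent that counting split their reads. There are 32285 gene identifiers in the HSC table and 56980 in that of macrophages. Names were taken from GENCODE M21 (GRCm38), which names all but 127 and 4907 of them. The unnamed identifiers took 0.0224% to 0.0352% of HSC reads and 3.93% to 5.91% of macrophage reads. The 2 mitochondrial ribosomal RNA genes took 6.84% to 12.7% of macrophage reads and 0% of HSC reads, so that levels are not compared between the tables. Of the per-sample columns, 0 were left without a sample.

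Depth was 51982064 to 77463770 reads per HSC library. The Cre positive macrophage libraries (2602934 to 5366990 reads) were shallower than the Cre negative ones (17230019 to 24658205 reads). A count of 3 corresponds to 0.0386 to 0.0561 CPM in HSC libraries, to 0.138 to 0.174 CPM in Cre negative and to 0.522 to 1.08 CPM in Cre positive macrophage libraries. This floor covers counting error only, since amplified reads without molecular identifiers are not independent molecules. The counts of libraries of 1 group differed by far more than sampling noise, with a chi-square per degree of freedom of 56.9 to 844, so none was taken for a second deposit of another. This does not show that they came from separate embryos.

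Each sort was analysed on its own table with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the genotype groups (13962 in HSCs and 17806 in macrophages), scaled by TMM and tested with robust quasi-likelihood fits (glmQLFit and glmQLFTest) of Cre positive minus Cre negative, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. CPM values use TMM-scaled library sizes, and means are given with the SD over 3 libraries. Standard errors were derived from the log2 fold change and the F statistic. The shares of reads taken by a gene list are of all counted reads. A lower bound for a gene at 0 throughout a group was computed as the mean CPM of the other group over the mean CPM of 3 counts per library. Jag1 was also tested by an exact two-sided permutation of log2(CPM + 1), which cannot go below 0.1 with 3 against 3 libraries. The difference of genotype effects was tested as an interaction of genotype and cell type in a fit of all 12 libraries over the 32210 identifiers shared by the tables, of which 20128 were kept. That fit took 1 spread estimate per gene over both sorts. Effects were compared between sorts by correlations of log2 fold changes.

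Before the data were examined, 35 gene lists (25 gene programmes and 10 cell types) and 1 control list of sex-linked genes were written down, and lists with at least 5 tested members entered camera with a correlation of 0.01, camera with an estimated correlation, and fry, with Benjamini-Hochberg adjustment over lists. The rule for named genes was fixed at the same time. It takes Jag1, then genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between groups, and, as fewer than 10 qualified, up to 10 genes per direction with the smallest unadjusted p under the same filters, leaving out sex-linked genes, predicted gene models and pseudogenes. In each described list it takes up to 3 members with the smallest p where none passed, and for the interaction the 5 genes with the smallest adjusted p per direction. It also takes the genes of the sort gates as levels. Further markers given as levels (Adgre1, Stab2, Lyve1, Alb, Hlf, Mecom and Malat1), and Epor in the interaction, were chosen after the data were seen.

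The alternatives tried were DESeq2 1.42.0, upper-quartile scaling, library totals, every gene with at least 1 read, at least 10 reads in every library of either group, limma-voom with quality weights, the replicate number as a block, a sex term, an adjusted p under 0.1 and leaving out each library. After the data were seen, thinning of the macrophage libraries to the depth of the shallowest, removal of mitochondrial ribosomal RNA and unnamed identifiers, and removal of pairs of Cre positive libraries that stood apart were added, the last leaving 1 library in that group. The tests were tried on simulated data with the real means, library sizes and dispersions, where 200 genes were changed. In the HSC simulation over 13962 genes, 2.4% of genes changed 2-fold, 37.6% changed 4-fold, 43.2% changed 8-fold and 61.2% changed 16-fold were called. For macrophages over 17806 genes these shares were 0.4%, 11.2%, 24% and 41.2%, and for an interaction simulated 2 times over the 12280 genes tested in both sorts, fewer than the 20128 of the real test, 0%, 1%, 7% and 31%. At most 8, 15 and 2 unchanged genes were called in any simulation. With no list changed, at most 1 list was called by camera, and a ribosomal protein list shifted by 1 on the log2 scale was called in 5 of 5 simulations of each sort; simulated genes were independent of each other, which real members of a list are not. Gene lengths, as the merged length of all annotated exons, and positions came from GENCODE M21.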

Results

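Gene expression was measured by bulk RNA sequencing in cells sorted from fetal livers of C57BL/6 mouse embryos at E14.5, when the liver is the main site of blood formation. All embryos carried floxed alleles of Jag1, which encodes the Notch ligand Jagged1, and either carried or lacked the Vav-Cre transgene, which drives recombination in blood cells. Hematopoietic stem cells (HSCs) were sorted as live CD45+ lineage- cKit+ Sca1+ CD48- CD150+ cells, and macrophages as CD169+ cells. Each of the 4 groups (HSC Cre negative, HSC Cre positive, macrophage Cre negative and macrophage Cre positive) had 3 libraries. The HSC libraries held 51982064 to 77463770 counted reads. The Cre negative macrophage libraries held 17230019, 24590240 and 24658205 reads and the Cre positive ones 2602934, 5237505 and 5366990, so that depth differed by genotype in this sort. The labels do not say whether the libraries of a group came from separate embryos, and p-values of single genes measure only the spread between these libraries. Those of camera with its preset correlation compare list members with other genes and take the members as nearly independent.

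The sorted populations were described by the level of the genes behind the gates and by markers of other fetal liver cells. In the HSC libraries Kit reached 40.1 to 183 CPM (counts scaled to TMM-corrected library size), Ly6a, which encodes Sca1, 127 to 190 CPM, and Slamf1, which encodes CD150, 8.04 to 74.4 CPM. Cd48, whose product was gated out, measured 12.6, 17.4 and 25.4 CPM in Cre negative libraries and 3.28, 8.53 and 0 CPM in those labelled Cre positive (edgeR unadjusted p = 0.238), so these libraries did not overlap in a gene of the gate. Ptprc, which encodes CD45, lay between 36.9 and 266 CPM. The HSC regulators Hlf and Mecom were counted in every HSC library, at 61.9 to 203 and 64.4 to 170 CPM. Sinusoidal endothelial transcripts were nevertheless abundant in this sort: Stab2 lay between 567 and 1569 CPM and Lyve1 between 1679 and 4262 CPM. The 21 endothelial markers together took 1.38% ± 0.442 (SD, n = 3) of reads in Cre negative and 1.08% ± 0.156 (n = 3) in Cre positive libraries. Other cell types were present too: macrophage markers took 0.385% ± 0.0248 and 0.461% ± 0.111 of HSC reads, Cre negative first. Hepatoblast markers took 0.269% ± 0.112 and 0.256% ± 0.0299. In the macrophage libraries Siglec1, which encodes CD169, lay between 16.2 and 117 CPM and the macrophage gene Adgre1 (F4/80) between 22.3 and 403 CPM, against 2455 to 5121 CPM for Stab2. Macrophage markers took 0.730% ± 0.370 of reads in Cre negative and 0.507% ± 0.199 in Cre positive macrophage libraries, and endothelial markers 1.27% ± 0.575 and 1.78% ± 0.274 (SD, n = 3 each). Cre negative replicate 1 of this sort, at 22.3 CPM of Adgre1, lay below all Cre positive libraries, and it held 1707 CPM of the hepatocyte gene Alb where the other 5 libraries held 77.1 to 232 CPM.

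The targeted gene was examined to see how far the labels show in the counts. Jag1 (ENSMUSG00000027276) lies on chromosome 2, from 137081456 to 137116644 on the minus strand of GRCm38. In macrophages Jag1 measured 33.3 ± 16.9 CPM in Cre negative and 5.79 ± 5.37 CPM in Cre positive libraries (SD, n = 3 each), and each Cre positive library (0, 10.6 and 6.79 CPM) lay below each Cre negative library (52.6, 21.1 and 26.3 CPM). Such a separation was not particular to Jag1: of 17806 genes tested in macrophages, 2107 lay lower and 405 higher in Cre positive libraries without overlap. For Jag1 the exact two-sided permutation test of log2(CPM + 1) gave p = 0.1, the smallest that 3 against 3 libraries allow, and edgeR's quasi-likelihood test gave a log2 fold change of -2.51 with a standard error (SE) of 1.42 (unadjusted p = 0.0946). The library at 0 has a floor of 1.08 CPM, the level of 3 counts, so that lower levels were not detectable there. The macrophage libraries also held endothelial transcripts, with Stab2 at 2455 to 5121 CPM. Which cells the Jag1 reads came from was not tested. In HSCs the gene was scarce and the groups overlapped: Cre negative libraries measured 6.53, 6.87 and 1.16 CPM, and the libraries labelled Cre positive 10.5, 0 and 19.5 CPM (exact permutation p = 0.8, n = 3 each). Jag1 thus did not separate the HSC groups, and 2 of the 3 libraries labelled Cre positive held a higher Jag1 level than any Cre negative library. A gene-level count also takes reads from exons outside the floxed part, so it bears on the genotype only in part. The sign of the HSC difference (0.29 on the log2 scale) turned negative on library totals with a pseudocount of 0.1 (-0.46) and without Cre negative replicate 3 (-0.32), Cre positive replicate 1 (-0.16) or Cre positive replicate 3 (-0.57), and it was 1.61 without Cre positive replicate 2.

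**Figure D1:**
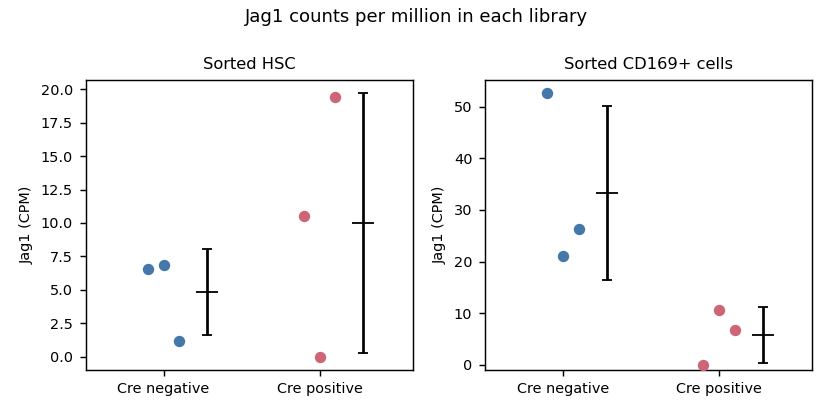
Jag1 in CPM (y axis) in each library, shown as points, of the Cre negative and Cre positive groups of sorted HSCs (left) and CD169+ cells (right), with the group mean and SD (n = 3) as a bar at the side. The 3 Cre positive CD169+ libraries lie between 0 and 10.6 CPM, below the 3 Cre negative ones, while in HSCs the libraries labelled Cre positive span 0 to 19.5 CPM.

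The HSC comparison asked how loss of Jag1 from blood cells alters the transcriptome of fetal liver HSCs. As a group, ribosomal protein genes rose in the HSC libraries labelled Cre positive, as did genes of oxidative phosphorylation, HSC identity and neutrophil granules, while markers of stellate and mesenchymal cells fell, each by the camera test with its preset correlation alone. Genes with reads numbered 16021, 15318 and 14315 in Cre negative libraries and 14386, 13645 and 12747 in those labelled Cre positive. The nuclear RNA Malat1 measured 4605 ± 1232 and 7758 ± 1240 CPM (SD, n = 3 each), without overlap (unadjusted p = 0.0114, adjusted p = 0.689). Of single genes, 0 of 13962 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the smallest adjusted p being 0.689. At an unadjusted p under 0.05 stood 892 genes, 338 with higher and 554 with lower levels, where chance would give 698. DESeq2, run on the same genes as an alternative, called 27 higher and 106 lower genes, and 66 of the lower ones had 0 reads in all 3 libraries labelled Cre positive. Genes whose libraries did not overlap between the groups made up 15.7% of those tested, where chance gives 10%.

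The genes with the smallest unadjusted p in HSCs did not pass and are given as values. Hif1a, the oxygen-regulated subunit of hypoxia-inducible factor 1 (chromosome 12, 73901375 to 73947530), measured 129 ± 6.64 CPM in Cre negative and 51.6 ± 4.28 CPM in the libraries labelled Cre positive (SD, n = 3 each), a log2 fold change of -1.32 (SE 0.23). Pecam1, an adhesion molecule of endothelium and blood cells (chromosome 11, 106654217 to 106750628), measured 320 ± 34.1 and 159 ± 18.1 CPM. Dnpep, an aminopeptidase, measured 150 ± 27.6 and 61.3 ± 8.09 CPM, and Ccn2, a matricellular protein also called CTGF, 189 ± 159 and 26.1 ± 8.25 CPM. Pipox, Pde1a, Kctd7, C1qtnf9 and Cpe had 0 reads in every library labelled Cre positive and means of 15.5, 15.2, 16.7, 16.5 and 12.4 CPM in Cre negative HSCs. Against a floor of 3 counts per library they were at least 333-fold, 327-fold, 359-fold, 355-fold and 266-fold lower, a bound for counting error only. Maob, a monoamine oxidase, had 25.5 ± 12.9 CPM in Cre negative libraries and 1 read in the libraries labelled Cre positive together, a ratio of 5019 with a 95% counting interval of 901 to 198256. On the other side stood Mdm4, a negative regulator of p53 (chromosome 1, 132959484 to 133030561), with 17.2 ± 5.85 CPM in Cre negative and 67.3 ± 11.1 CPM in libraries labelled Cre positive (log2 fold change 1.97, SE 0.40). Insr, the insulin receptor, measured 20.3 ± 1.64 and 66.5 ± 18.9 CPM. Agap2 measured 5.58 ± 1.16 and 30.6 ± 1.91 CPM, Plac8 20.6 ± 4.16 and 69.6 ± 26 CPM, and the chromatin gene Bptf 61.4 ± 7.91 and 126 ± 18.9 CPM. Nudt16, Mphosph8, Rapgef1, Fbxl7 and Snhg17 completed the 10 genes on this side, with log2 fold changes of 1.11, 1.12, 1.31, 1.20 and 1.44. These genes had adjusted p-values of 0.689 in edgeR.

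Of the 34 gene lists tested in HSCs, 5 rose and 1 fell in the libraries labelled Cre positive by camera with its preset correlation of 0.01, and 0 with an estimated correlation, the smallest adjusted p then being 0.761. Fry, which tests whether members move one way, called 0 lists. Over all genes tested, 0 members of any list passed. Ribosomal protein genes, the structural parts of the ribosome, rose with a median log2 fold change of 0.58: 77 of 79 members had the higher mean in the libraries labelled Cre positive (adjusted p = 7.57e-30; adjusted p = 0.761 with an estimated correlation). Among them Rpl10a measured 99.4 ± 11.7 and 180 ± 26 CPM, Rps7 155 ± 6.64 and 255 ± 33.1 CPM, and Rpl36 109 ± 17.9 and 198 ± 53.4 CPM, Cre negative value first. Nuclear genes of oxidative phosphorylation rose with a median of 0.34, 62 of 76 members having the higher mean (adjusted p = 1.01e-05; adjusted p = 0.761 with an estimated correlation). Uqcrh measured 101 ± 7.39 and 157 ± 15.7 CPM and Ndufb7 136 ± 14.3 and 220 ± 73.8 CPM, while Ndufs1, another subunit gene, measured 202 ± 26.1 and 111 ± 21 CPM. The 7 mitochondrially encoded genes tested had a median of 0.55 and all had the higher mean in the libraries labelled Cre positive (adjusted p = 0.000103; adjusted p = 0.761 with an estimated correlation). They moved together (estimated correlation 0.927), and 1 of the 7 separated the groups. The share of reads of this list overlapped, at 0.387% to 0.590% in Cre negative libraries and 0.565% to 0.860% in those labelled Cre positive. Without Cre positive replicate 3 its camera adjusted p was 0.0464 with the preset correlation. The call on nuclear oxidative phosphorylation genes ended without Cre positive replicate 3 (adjusted p = 0.202).

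HSC identity genes rose with a median of 0.34, 35 of 50 members having the higher mean (adjusted p = 0.00612, and adjusted p = 0.761 with an estimated correlation). Their share of reads overlapped between the groups, at 0.565% ± 0.146 in Cre negative libraries and 0.600% ± 0.0610 in those labelled Cre positive. That of endothelial markers was 1.38% ± 0.442 and 1.08% ± 0.156 (SD, n = 3 each). The members with the smallest p did not move one way: Kmt2a, a histone methyltransferase, measured 51.1 ± 9.02 CPM in Cre negative libraries and 148 ± 82.6 CPM in those labelled Cre positive. The angiopoietin receptor gene Tek measured 314 ± 59 and 173 ± 45.7 CPM and the junction gene Esam 936 ± 289 and 582 ± 54.9 CPM, both genes that endothelial cells also express. The HSC identity call ended without Cre negative replicate 1 (adjusted p = 0.361), Cre negative replicate 2 (0.0592) or Cre positive replicate 2 (0.0920). Neutrophil and granule markers had the higher mean in 16 of 16 members, with a median of 0.71 (adjusted p = 0.00735; adjusted p = 0.761 with an estimated correlation). S100a8 measured 163 ± 28.4 and 347 ± 276 CPM and S100a9 201 ± 51.7 and 396 ± 341 CPM. This call ended without Cre negative replicate 1 (0.0838), Cre positive replicate 1 (0.192) or Cre positive replicate 2 (0.849). Stellate and mesenchymal markers fell with a median of -0.21, 15 of 19 members having the lower mean (adjusted p = 0.0431; adjusted p = 0.761 with an estimated correlation). Its leading members were the matrix genes Lum, at 126 ± 51.9 and 44.4 ± 24.3 CPM, and Postn, at 94.2 ± 34.7 and 40.5 ± 15.9 CPM, and the chemokine Cxcl12, at 96 ± 22.7 and 38.8 ± 24.2 CPM. That call ended without Cre negative replicate 2 (0.234), Cre negative replicate 3 (0.0571), Cre positive replicate 1 (0.106) or Cre positive replicate 2 (0.749).

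The Notch lists did not pass in HSCs. Of 30 Notch receptors, ligands and processing genes, 14 had the higher and 16 the lower mean in libraries labelled Cre positive (median -0.04, adjusted p = 0.781), and 0 passed when adjusted over the list alone. Ncstn, a part of gamma-secretase, measured 332 ± 79 and 209 ± 11.2 CPM, and Numb, a Notch antagonist, 112 ± 23.9 and 61.9 ± 17.5 CPM. Of 20 Notch target genes 12 had the lower mean (median -0.41, adjusted p = 0.278, 0 adjusted over the list alone), with Myc at 298 ± 42.8 and 199 ± 7.1 CPM. Macrophage markers (31 tested, adjusted p = 0.526), erythroblastic island and iron genes (28 tested, adjusted p = 0.344) and HSC-supportive factors (17 tested, adjusted p = 0.526) did not pass either. Their leading members were Spic at 55.2 ± 10.2 and 26.8 ± 0.666 CPM, Lyz2 at 522 ± 177 and 944 ± 188 CPM, and Cxcl12 as above. The other 23 of the 28 lists not called had adjusted p-values of 0.0755 (endothelial markers) to 0.975 (glycolysis), and 4 of them (endothelial markers, adhesion and niche interaction, hypoxia response, and monocyte and dendritic cell markers) had 1 member each passing when adjusted over the list alone, Pecam1 among them.

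The macrophage comparison asked the same of CD169+ macrophages, which lie in erythroblastic islands of the fetal liver. In Cre positive libraries ribosomal protein genes fell, as did genes of oxidative phosphorylation, the erythroblastic island, antigen presentation, efferocytosis and macrophage identity and markers of stellate and erythroid cells. Endothelial markers and G2/M genes rose. These calls were made by camera with its preset correlation alone. After thinning to equal depth, genes with reads numbered 18718, 29368 and 26172 in Cre negative libraries and 14655, 19645 and 15407 in Cre positive ones. No single gene passed: 0 of 17806 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.225), with 965 genes at an unadjusted p under 0.05, 91 with higher and 874 with lower levels, where chance would give 890. DESeq2 called 10 higher and 51 lower genes. Genes whose macrophage libraries did not overlap between the groups made up 14.1% of those tested (405 higher, 2107 lower), where chance gives 10%. The median log2 fold change over all genes was -0.16 with TMM scaling, -0.00 with upper-quartile scaling and 0.05 on library totals, and the list medians that follow are read against that of -0.16. In each of them the direction was the same with upper-quartile scaling. The count of called genes was 7 without Cre negative replicate 1, 1 without Cre negative replicate 2, 1 without Cre negative replicate 3, 4 without Cre positive replicate 1, 1 without Cre positive replicate 2 and 34 without Cre positive replicate 3.

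The genes with the smallest unadjusted p in macrophages did not pass and are given as values, Cre negative first (SD, n = 3 each). Apoe, the apolipoprotein E gene (chromosome 7, 19696109 to 19699188), measured 4646 ± 1435 and 2126 ± 454 CPM, a log2 fold change of -1.13 (SE 0.28). Ccl6, a chemokine of myeloid cells, measured 114 ± 82.2 and 10.4 ± 5.2 CPM, and Taf7, a subunit of the general transcription factor TFIID, 50 ± 36.8 and 1.63 ± 1.22 CPM. Rbp4, the plasma retinol carrier, measured 69.7 ± 92.8 CPM, the immunoproteasome gene Psmb10 36 ± 28.1 CPM, Cyp2e1 42.7 ± 64.9 CPM and Gpt2 29.1 ± 19.3 CPM in Cre negative libraries, against 1 read each over the Cre positive libraries together. These ratios were 969 (95% counting interval 174 to 38256), 500 (89.8 to 19754.5), 593 (106 to 23424) and 404 (72.6 to 15968). The intervals leave out the spread between libraries, and the SD of Rbp4 and Cyp2e1 exceeded their means. Cre negative replicate 1 also held 1707 CPM of the hepatocyte gene Alb, and its part in these ratios was not tested. Sephs2, of selenocysteine synthesis, had 0 reads in the Cre positive libraries, at least 33.7-fold lower against a floor of 3 counts per library. The histone gene Hist4h4 measured 38 ± 20.4 and 0.290 ± 0.502 CPM. In the other direction Myo6, an actin motor, measured 102 ± 13.5 and 303 ± 161 CPM, and Foxo1, a forkhead transcription factor (chromosome 3, 52268336 to 52353221), 54.5 ± 5.81 and 155 ± 51.2 CPM (log2 fold change 1.51, SE 0.45). Fam208b measured 53.7 ± 9.03 and 150 ± 30.5 CPM, and Cenpc1, a centromere protein, 50.5 ± 3.95 and 125 ± 16 CPM. Zfp827, Prr11 and Tmem263 had log2 fold changes of 1.67, 2.03 and 1.81. The homeobox genes Hoxa2 and Dlx2 were near 0 in Cre negative libraries (0.810 ± 0.702 and 0.0156 ± 0.0270 CPM) and reached 37.7 ± 42.4 and 8.88 ± 4.28 CPM in Cre positive ones (Dlx2 ratio 536, interval 96.3 to 21183.5, with 1 Cre negative read), and Atp6v1fnb, with 0 Cre negative reads, was at least 46.4-fold higher.

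Of the 35 lists tested in macrophages, 2 rose and 8 fell by camera with the preset correlation, and 0 with an estimated one (smallest adjusted p = 0.718). The number called was 5 without Cre negative replicate 2, 6 without Cre negative replicate 3 and 2 without Cre positive replicate 2. Ribosomal protein genes fell with a median of -0.72, 74 of 77 members having the lower mean (adjusted p = 1.05e-07; adjusted p = 0.718 with an estimated correlation). Rps29 measured 347 ± 127 and 143 ± 8.91 CPM and Rplp1 1140 ± 500 and 537 ± 111 CPM. The share of reads of ribosomal protein genes overlapped, at 2.28% to 3.76% in Cre negative and 2.20% to 2.53% in Cre positive libraries. Nuclear oxidative phosphorylation genes fell with a median of -0.67, 62 of 76 lower (adjusted p = 0.00212; adjusted p = 0.718 with an estimated correlation). Ndufs5 had 20 ± 6.91 CPM in Cre negative libraries and 0 reads in Cre positive ones, and Ndufs7 measured 83.8 ± 52.3 and 12.5 ± 10.2 CPM. This list was no longer called without Cre negative replicate 2 (adjusted p = 0.0622) or Cre positive replicate 2 (0.0605). Endothelial markers rose with a median of 0.28, 17 of 21 higher (adjusted p = 0.000212; adjusted p = 0.718 with an estimated correlation). The endothelial phosphatase gene Ptprb measured 726 ± 398 and 1174 ± 140 CPM and Tek 430 ± 89.5 and 611 ± 94.6 CPM. Their list was not called without Cre positive replicate 2 (0.0605). G2/M genes rose with a median of 0.17, 30 of 48 higher (adjusted p = 0.00564; adjusted p = 0.718 with an estimated correlation). The member with the smallest p, the mitotic kinase Aurka, went the other way, at 70.7 ± 11.5 and 27.6 ± 4.06 CPM. That call ended without Cre negative replicate 2 (0.0930), Cre negative replicate 3 (0.128), Cre positive replicate 1 (0.140) or Cre positive replicate 3 (0.0670).

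Macrophage markers fell with a median of -1.10, 28 of 30 members having the lower mean in Cre positive libraries (adjusted p = 0.0169; adjusted p = 0.758 with an estimated correlation). The fractalkine receptor Cx3cr1 measured 150 ± 85.6 and 31.9 ± 28 CPM and the apoptotic-cell receptor Axl 242 ± 166 and 69.6 ± 51.2 CPM. Their libraries overlapped between the groups, with 1 of 30 members separated. Macrophage markers were not called without Cre negative replicate 2 (adjusted p = 0.630), Cre negative replicate 3 (0.552), Cre positive replicate 1 (0.374) or Cre positive replicate 2 (0.575). Erythroblastic island and iron genes fell with a median of -1.01, 24 of 27 lower (adjusted p = 0.00564; adjusted p = 0.718 with an estimated correlation). Dnase2a, the nuclease that digests expelled erythroblast nuclei, measured 44.8 ± 36.9 and 0.868 ± 1.5 CPM, and the transferrin gene Trf 562 ± 600 and 115 ± 46.8 CPM. The SD of Trf exceeded its mean in Cre negative libraries. Without Cre positive replicate 1 or 2 the island genes were not called, with adjusted p-values of 0.140 and 0.157. Antigen presentation genes fell with a median of -1.05, 16 of 17 lower and 2 passing when adjusted over the list alone (adjusted p = 0.00782; adjusted p = 0.718 with an estimated correlation). Besides Psmb10, the class I genes H2-D1 and H2-K1 measured 225 ± 68.8 and 80.8 ± 36.6 CPM, and 91 ± 29.4 and 33.2 ± 13.1 CPM. Antigen presentation was not called without Cre negative replicate 2 (0.121) or Cre positive replicate 2 (0.256). Efferocytosis and lysosome genes fell with a median of -0.80, 35 of 42 lower (adjusted p = 0.0169; adjusted p = 0.758 with an estimated correlation). The lysosomal gene Psap measured 688 ± 217 and 287 ± 180 CPM and the cathepsin Ctsz 289 ± 140 and 107 ± 49.8 CPM. This call ended with upper-quartile scaling (0.0590) and without Cre negative replicate 2 (0.211), Cre negative replicate 3 (0.333), Cre positive replicate 1 (0.374) or Cre positive replicate 2 (0.466).

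Markers of 2 further cell types fell in Cre positive macrophage libraries by camera with the preset correlation, but their shares of reads overlapped between the groups. Stellate markers took 0.356% ± 0.193 and 0.333% ± 0.0562 of reads, Cre negative first, and erythroid markers 0.0774% ± 0.00844 and 0.0898% ± 0.0410 (SD, n = 3 each). The stellate share mostly reflects Col4a1 and Col4a2, which endothelial cells also express. As a fraction of the summed stellate CPM they made up 0.680 to 0.854 in Cre negative and 0.908 to 0.940 in Cre positive libraries. Stellate and mesenchymal markers had a median of -1.06, 14 of 18 lower (adjusted p = 0.0169; adjusted p = 0.718 with an estimated correlation). The collagen gene Col1a2 measured 108 ± 145 and 17.6 ± 15.7 CPM and Col3a1 259 ± 331 and 15 ± 18 CPM. Stellate markers were not called without Cre negative replicate 1 (0.288), Cre positive replicate 2 (0.177) or Cre positive replicate 3 (0.188). Erythroid markers had a median of -1.02, 17 of 24 lower (adjusted p = 0.0169; adjusted p = 0.718 with an estimated correlation). Alas2, of heme synthesis, measured 25.9 ± 16.5 and 0.584 ± 0.856 CPM. The erythroid call ended with thinning to equal depth (0.0751) and without Cre negative replicate 2 (0.174), Cre negative replicate 3 (0.237), Cre positive replicate 1 (0.599) or Cre positive replicate 2 (0.283). Notch receptors, ligands and processing genes (30 tested, median 0.11, adjusted p = 0.178) and Notch targets (22 tested, median -0.23, adjusted p = 0.794) did not pass. HSC-supportive factors (20 tested, median -0.22, adjusted p = 0.688) and HSC identity genes (45 tested, median 0.31 but mean -0.25, adjusted p = 0.150) did not pass either. Numb measured 127 ± 20.1 and 230 ± 15.3 CPM and the Notch target Hes1 32.8 ± 15.9 and 9.43 ± 13.2 CPM. The stem cell factor gene Kitl measured 56.5 ± 13.7 and 38 ± 1.11 CPM, and Angptl4, with 0 Cre positive reads, was at least 27.7-fold lower. The other 21 of the 25 lists not called had adjusted p-values of 0.133 (fatty acid oxidation) to 0.883 (monocyte and dendritic cell markers). Adjusted over the list alone, 2 members passed among NF-kB and inflammatory cytokines, 1 among hepatoblast markers and 1 among HSC-supportive factors.

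**Figure D2:**
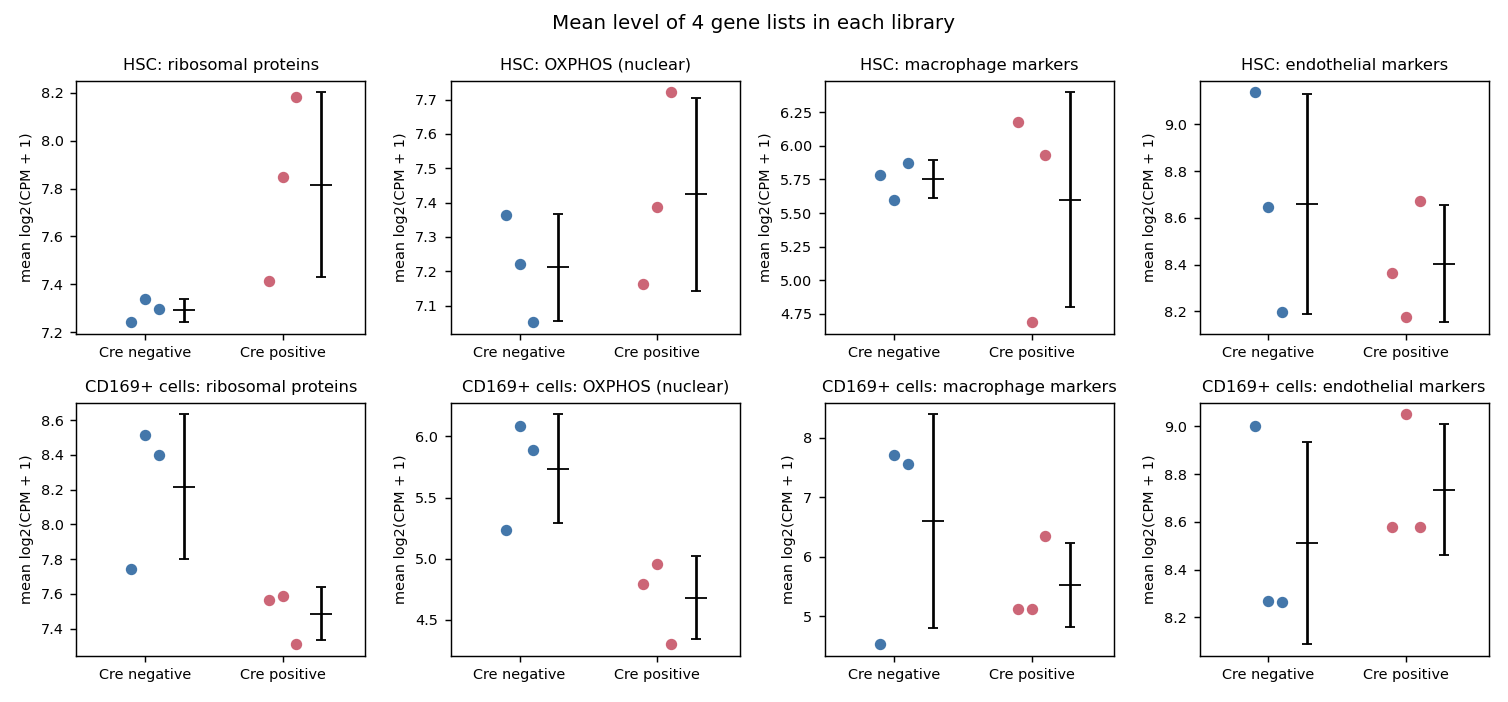
Mean log2(CPM + 1) of the tested members of 4 gene lists (y axis) in each library (points) of the Cre negative and Cre positive groups, with the group mean and SD (n = 3) as a bar at the side, in HSCs (top) and CD169+ cells (bottom). Each y axis has its own range; among CD169+ cells, macrophage markers lie at 4.53 in Cre negative replicate 1, below the 5.12 to 6.35 of the Cre positive libraries.

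Whether the genotype difference itself differed between the cell types was tested on 20128 genes in all 12 libraries. Of these, 14 passed edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment, all with a lower genotype effect in macrophages than in HSCs, and 1736 had an unadjusted p under 0.05. The smallest adjusted p belonged to Sephs2 and Tmem256 (adjusted p = 0.000902 each), followed by Psmb10 (0.00307), the gene model 1810037I17Rik (0.00307) and Mycn (0.00427). As means of 3 libraries, Cre negative first, Sephs2 measured 157 and 118 CPM in HSCs and 24.3 and 0 CPM in macrophages. Tmem256 measured 70.2 and 141 CPM in HSCs and 18.2 and 0 CPM in macrophages, and Mycn, a MYC family transcription factor, 364 and 345 CPM in HSCs and 6.16 and 0 CPM in macrophages. The set also held the erythropoietin receptor gene Epor, with 7.70 CPM in Cre negative macrophages and 0 reads in Cre positive ones, the sort with the lowest depth. The count was 10 with macrophage libraries thinned to equal depth, and DESeq2 called 299 genes with a higher and 448 with a lower effect in macrophages. Without single HSC libraries the count was 9 (Cre negative replicate 1 or 2), 8 (Cre negative replicate 3) and 6 (Cre positive replicate 3). Without single macrophage libraries it was 23 (Cre negative replicate 1), 108 (Cre positive replicate 1), 210 (Cre positive replicate 2) and 104 (Cre positive replicate 3). In the interaction fit both sorts shared 1 spread estimate per gene, unlike in the separate fits. The part of that sharing in the calls was not tested. In the separate macrophage fit 0 of 17806 genes passed the quasi-likelihood test (smallest adjusted p = 0.225).

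Genotype effects in the 2 cell types were compared across 12280 genes tested in both. Pearson's r of the log2 fold changes was 0.0166 and Spearman's rho 0.00246, over genes, which are not independent replicates. Their signs matched in 50.6% of genes. At an unadjusted p under 0.05 in both stood 46 genes, where the product of both rates gives 41.6, and 19 of them shared a sign. With 0 genes called in either cell type, no overlap of calls could be counted.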

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

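Of the tests in this part, leaving out single libraries, thinning to equal depth, the endothelial covariate with its criterion and calls of the list over other splits were chosen after the ribosomal protein result was seen; the length-matched lists and the count of interaction genes over other splits were chosen before. Gene groups whose genotype effect differed between the cell types, by a test of the interaction with the preset correlation, numbered 7 of 35. Ribosomal protein genes had a lower effect in macrophages than in HSCs, with a median interaction of -1.30 on the log2 scale (adjusted p = 4.02e-26; adjusted p = 0.505 with an estimated correlation). Nuclear oxidative phosphorylation genes (median -0.80, adjusted p = 1.52e-08; adjusted p = 0.505 with an estimated correlation) and mitochondrially encoded genes (median -1.13, adjusted p = 0.00153; adjusted p = 0.641 with an estimated correlation) had the same direction. So had antigen presentation genes (median -1.61, adjusted p = 0.00753; adjusted p = 0.505 with an estimated correlation) and erythroblastic island and iron genes (median -0.72, adjusted p = 0.0381; adjusted p = 0.505 with an estimated correlation). Endothelial markers (median 0.44, adjusted p = 0.000214; adjusted p = 0.799 with an estimated correlation) and TGF-beta and BMP genes (median 0.26, adjusted p = 0.0483; adjusted p = 0.573 with an estimated correlation) had a higher effect in macrophages.

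Ribosomal protein genes were higher in the HSC libraries labelled Cre positive (median 0.58) and lower in Cre positive macrophages (median -0.72). Among 10000 random lists matched on length and level the HSC median lay above all (percentile 100, matched median 0.06). The macrophage median lay below all (percentile 0, matched median -0.35). Matching used the merged length of all annotated exons (list median 1770 in HSCs), which is not transcript length. Random members were drawn independently, whereas those of this list moved together (estimated correlation 0.695 in HSCs and 0.347 in macrophages). Short transcripts as the cause are therefore not decided. Leaving out any 1 HSC library kept the call (highest adjusted p 3.27e-13 by camera with the preset correlation). That test also called 7 of 9 other splits, so it cannot count against 1 library as the cause. In macrophages the median relative to all genes was -0.54 after thinning and -0.57 before. Random thinning leaves the expected level of well-counted genes unchanged, so the kept median argues against read depth alone for such genes. Thinning cannot decide on lower input or complexity. With the endothelial list as a covariate the HSC median went from 0.59 to 0.66, but it was 0.32 without Cre positive replicate 3. Endothelial content in HSCs is not decided by this. The list stayed called there by the preset correlation alone, which also called 7 of 9 other splits (adjusted p = 0.916 by camera with an estimated correlation). The macrophage median went from -0.57 to -0.28 (bootstrap SD 0.0593). It was -0.76 without Cre negative replicate 1 and -0.14 without Cre positive replicate 3. In macrophages endothelial content and genotype cannot be told apart, since a share of 0.499 of the median was kept. The macrophage list was still called by camera with the preset correlation alone (adjusted p = 0.00445, and at most 0.0230 without any 1 library). With an estimated correlation its adjusted p was 0.780. A genotype effect may remain as a hypothesis, but Jag1 was not lower in 2 of the 3 HSC libraries labelled Cre positive, reads shared with pseudogenes were not tested, differences in RNA quality were not excluded, and other splits also called the list, 7 of 9 in HSCs (smallest adjusted p = 3.45e-25) and 3 of 9 in macrophages, where setting Cre negative replicate 1 with Cre positive replicates 2 and 3 against the rest gave a smaller adjusted p (1.46e-09) than the genotypes did (1.05e-07).

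For single genes the interaction was called in 14, all with a lower effect in macrophages, 8 of them at 0 reads in every Cre positive macrophage library. In 60 drawn splits of the libraries within each cell type, the real one included, 2 gave at least 14 genes, the highest other giving 15; the number of draws was raised after a smaller draw had been seen. That share is under 0.05. It cannot tell genotype from depth, since the real split also sets the shallow macrophage libraries against the deep ones. The splits were run at deposited depth only, and 8 of the 14 genes stayed called after thinning the macrophage libraries. Signal outside the main comparisons was found in sex-linked genes. HSC Cre positive replicate 3 held 18.5 CPM of Xist, which is expressed from an inactive X chromosome, beside 125 CPM of Y-linked genes, whereas HSC Cre negative replicate 2 and Cre positive replicate 2 held 0 CPM of Xist beside 196 and 204 CPM.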

How the results depend on the processing

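The removal of pairs of libraries, thinning to equal depth, removal of mitochondrial ribosomal RNA and leaving out libraries from the correlation of effects were chosen after the data were seen. In HSCs 0 genes were called under upper-quartile scaling, library totals, other filters, limma-voom, a sex term, an adjusted p under 0.1 and without any single library, but 133 by DESeq2 and 1 without Cre positive replicates 2 and 3, which leaves 1 library in that group and takes the spread from the other. In macrophages the count was 61 by DESeq2 (10 higher, 51 lower), 21 with every gene of at least 1 read, 499 without Cre positive replicates 1 and 3 (82 higher, 417 lower, again with 1 library in that group), 1 to 34 without single libraries, and 0 after thinning. The HSC lists called numbered 0 with an estimated correlation, 0 by fry and 4 to 8 without single libraries; the macrophage lists 0, 0 and 2 to 13. Without those pairs the calls on HSC identity (adjusted p = 0.153), nuclear oxidative phosphorylation (0.808), mitochondrially encoded (0.201) and stellate genes (0.153) ended in HSCs, and those on G2/M (0.849) and stellate genes (0.245) in macrophages. The interaction gave 107 genes with every gene of at least 1 read, 747 by DESeq2 and 6 to 210 without single libraries. Pearson's r between the cell types was -0.00995 at a mean of at least 10 CPM in both and 0.00944 to 0.0358 without single libraries. The cause of these changes was not tested.

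The Jag1 difference in HSCs was -0.46 on library totals with a pseudocount of 0.1 and -0.57 to 1.61 without single libraries (-0.32 without Cre negative replicate 3 and -0.16 without Cre positive replicate 1), and its log2 fold change was -2.77 in limma-voom. In macrophages the Jag1 difference was -3.51 to -1.74 without single libraries. The log2 fold change of S100a9 in HSCs was -0.0103 without Cre positive replicate 2 and up to 1.32 without another. Of 780 values of 52 named HSC genes under 15 alternatives, 757 kept their direction and side of the threshold, 21 passed it (all by DESeq2) and 2 turned. Of 1034 for 62 macrophage genes, 970 did so and 64 passed it (16 by DESeq2).

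The labels do not pair libraries by replicate number. Deviations of equal-numbered libraries correlated at 0.0211, -9.32e-05 and -0.000502 in HSCs and 0.0366, 0.00842 and 0.0212 in macrophages, although 5 of the 6 equal-numbered pairs matched in whether Y-linked genes or Xist stood higher. With the number as a block, 0 HSC genes, 13 macrophage genes and 96 interaction genes were called, 6 and 10 lists were called, and r between the cell types was 0.103. The blocked exact test of Jag1 gave p = 0.75 for a difference of 0.29 in HSCs and p = 0.25, the smallest it can give, for -2.83 in macrophages.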

Other observations

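The tests of gene lists at full depth and the counts of called lists over splits were chosen before the results were seen, and the other tests in this part, with their criteria, after. In HSCs the immunoproteasome genes Psmb9, Psmb8 and Psmb10, which cleave proteins into peptides for antigen presentation, led their list without passing. Psmb9 measured 33.9 ± 4.72 CPM in Cre negative libraries and 81.3 ± 27.2 CPM in those labelled Cre positive, Psmb8 64.3 ± 11.5 and 121 ± 36.7 CPM, and Psmb10 85.5 ± 13.5 and 135 ± 24.3 CPM (SD, n = 3 each). The list did not pass camera (adjusted p = 0.223) but passed fry's test of change in either direction (adjusted p = 0.0083).

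Genes with a mean of at least 5 CPM in the 3 libraries of Cre negative HSCs and 0 reads in all libraries labelled Cre positive numbered 32, against 0 the other way round, and the highest count for another set of 3 libraries was 21. In macrophages these counts were 247 and 2, and the highest for another set was 328. Lower complexity of the Cre positive libraries remains a candidate explanation. The HSC count was 7.21 times the number given by independent misses at each library's own rate, inside the range of other sets of 3, which reached 278 at a very small denominator. The macrophage ratio after thinning was 1.54 (211 against 137 genes), with other sets up to 25.6, and a genotype effect on single genes was not excluded.

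Macrophage markers were lower and endothelial markers higher in Cre positive libraries of the CD169+ sort. The median of macrophage markers relative to all genes was -0.94 before and -0.96 after thinning. Their list was still called by camera with the preset correlation (adjusted p = 0.00300). At full depth that call was lost with an estimated correlation (adjusted p = 0.758) and without 4 of the 6 single libraries (0.374 to 0.630). Random thinning leaves the expected level of well-counted genes unchanged, so the kept median argues against read depth alone for such genes. Lower input or complexity as the cause is not decided. Whether macrophages were replaced by all other cell types alike was not settled, since in summed CPM the stellate ratio alone separated the groups. After thinning, log2 of summed endothelial over summed stellate CPM was 1.86 ± 0.134 in Cre negative and 2.43 ± 0.177 in Cre positive libraries (SD, n = 3 each). The lowest Cre positive library lay 0.229 above the highest Cre negative one, and 0.843 above it without Col4a1 and Col4a2. Endothelial cells also express these genes, which lead the stellate sum. In summed CPM the ratios to erythroid (4.06 ± 0.686 and 4.47 ± 0.717) and hepatoblast markers (3.71 ± 1.10 and 4.61 ± 0.601) overlapped. As a difference of mean log2(CPM + 1) after thinning, the endothelial and hepatoblast lists did separate the groups. The lowest Cre positive library then lay 0.419 above the highest Cre negative one. The same difference to erythroid markers overlapped (-1.14). Chance separates 3 against 3 libraries in 10% of cases. Genotype and variation in sort content between libraries cannot be told apart, because the lowest Cre negative library (4.53) lay below the highest Cre positive library in mean log2(CPM + 1) of macrophage markers, by -1.81. The gate for CD169 would remove most endothelial cells, yet Stab2 stood at 2455 to 5121 CPM in all 6 libraries, so the sorts may hold endothelial RNA in amounts that vary by library.

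The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For HSC genes the real count was 0, which every split reaches, and the highest other 1. For HSC lists the real count was 6 and the highest other 10, with 8 splits giving as many. For macrophage genes the real count was 0 and the highest other 51, from the split that set Cre negative replicate 1 with Cre positive replicates 1 and 2 against the rest, which points to a structure of the samples. For macrophage lists the real count was 10 and the highest other 12, with 3 splits giving as many.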
